A study of Mus musculus with 20 samples.

How the data were processed

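Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in mouse hepatocytes, the main parenchymal cells of the liver, isolated by perfusion from young mice (5 months, C57BL/6N) and old mice (23 months, C57BL/6J). The series lists 20 samples, of which 10 are H3K27ac libraries, 5 per age, and 10 are input samples, 5 per age. The region lists of the 10 H3K27ac libraries were analysed. No separate file of an input sample was analysed here, and the input entered only through the input value given for each region inside those lists. Per the labels' protocols, human chromatin had been added as a spike-in. Values scaled to it were not analysed here, so differences in the total amount of acetylation between ages cannot be derived. Age and substrain coincide in the labels, and no comparison below separates them. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples, part of which may be technical.

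Per the file headers, the authors called regions with HOMER in its histone mode, separately for each library against its own input, with no pooling. Individual peaks of 500 bp at a minimum distance of 1000 bp were stitched into regions. A region needed 4-fold more tags than the input at a Poisson p of 1e-04, and 4-fold more than the surrounding 10000 bp. The genome build was mm10, per the submitters' processing notes. The aligner and the version of HOMER are not given in the sources used here. The signal value of each region was its tag number scaled by the authors to 10000000 tags per library. The unscaled tags per region, deposited by the authors with no further normalization per the file headers, came in steps of 0.5 and were taken for expected counts. The score of each region was the authors' own HOMER score and served only to rank and filter regions within a list. The input value was a signal scaled by the authors to the depth of the matched library, and the fold over input was a ratio given by the authors with a minimum of 4. The length of each region, an other unit in bp, was deposited with it and equalled end minus start. Total tags, the share of tags in called regions (IP efficiency) and the estimated fragment length were read from the file headers. Total tags ranged from 6295930 to 15544145 per library. Coordinates are those of the lists. The smallest scaled values are close to the calling threshold, and the absence of a call does not show the absence of signal.

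Regions of the 10 lists were merged where they overlapped by at least 1 bp, which gave 46767 merged regions. The 31747 called in at least 2 libraries were kept as consensus regions, and 12550 of them were called in all 10. A library's value in a consensus region was the sum of the scaled tags of its regions inside it. Because each library brought its own region borders, that sum rises with the called length, and tags per kb of called length were computed as an alternative. The gene table used was GRCm38.p6, the assembly to which mm10 corresponds, and held no strand. A promoter could therefore not be told from the other end of a gene, and a gene-end region was defined instead as a consensus region within 1 kb of either annotated end of one of 21887 protein-coding genes. Where a gene had several, the one with the most tags was used. Regions inside a gene and away from its ends were classed as gene body and the rest as intergenic.

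The number of called regions, the genome covered and the IP efficiency were compared between ages by exact permutation tests over all 252 assignments of the libraries. These tests were two-sided, and their smallest possible p was 0.0079. The Jaccard index of each pair of lists was computed by base pairs with bedtools 2.31.1. Its mean within ages minus between ages was compared with that of every split of the libraries into equal groups in a one-sided exact test. Regions called in 5 libraries of one age and 0 of the other were counted, with a two-sided Fisher exact test per region. Signal in regions called in all 10 libraries was tested with limma 3.58.1 with a mean-dependent prior on log2 of scaled tags plus 1, after each library had been centred on the median of these regions, with Benjamini-Hochberg adjustment at 0.05. Log2 differences are old minus young on that scale and understate changes of weak regions. Counts from edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the expected counts, rounded to whole numbers, served as alternatives. Gene lists were tested with limma's camera against all other gene-end regions with a preset correlation of 0.01, with an estimated correlation and with fry beside it, and with adjustment over the 22 lists that had at least 3 tested regions. R 4.3.3, Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. On simulated tags for 12550 regions and 5 libraries per age, the limma step recovered 19.4% of regions changed by 1.5-fold, 61.2% at 2-fold and 90.9% at 4-fold, with 5 false calls among 119. In the same simulation a planted list of 20 regions was called and 0 of 20 unchanged lists were. Simulated regions varied independently of each other, so this does not show how often camera calls unchanged lists whose regions vary together. Simulated libraries also had no difference in IP efficiency and no region borders of their own, so the false calls of limma in the real data may be more. In the real data, splits of the libraries that mixed the ages gave up to 12 lists past the threshold. On simulated calls over 31747 regions, 200 of 200 planted regions of one age were found, with 8 others. The planting as 5 against 0 made that recovery certain, so it checks only the counting. The other calls were drawn independently, whereas splits of the real libraries other than by age gave a median of 11 and up to 49.

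The groups, the tests, the alternatives, 27 lists of genes and the rule for the genes named were fixed before the data were examined. The lists cover interferon signalling, inflammation, liver metabolism, transcription factors, the clock, stress, growth, sex-biased genes, other liver cell types and controls, and 678 of their 679 genes matched the gene table. The rule named the 8 gene-end regions with the largest difference in each direction among those past the threshold whose values did not overlap between ages. It added the 4 members with the smallest adjusted p of each of the 3 interferon lists and of the 4 other lists with the smallest camera p, up to 2 members of any other list, the 5 gene-end regions per direction with the most tags among those called at one age only, and the controls. Some genes that the rule named are not reported here. The alternatives were a replicate block, stricter or equally long region lists, other overlap rules, other scalings, tags per kb, another pseudocount and filter, IP efficiency as a covariate for the regions, and leaving out each library in turn. The test of IP efficiency itself, IP efficiency as a covariate for the lists, cyclic loess scaling, subtraction of the input, library weights, lists over whole gene spans and leaving out young replicates 1 and 3 together were chosen after seeing the data. No pair of libraries of one age held identical values.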

Results

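The data comprised lists of H3K27ac regions from 5 libraries of young and 5 of old mouse hepatocytes. Each library contributed between 21213 and 30195 regions covering 34.33 to 58.95 Mb of the mm10 genome, from 6295930 to 15544145 tags. Regions of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were called in all 10 libraries and no region was called at Xist, the RNA that silences an X chromosome in females. The gene ends of albumin (Alb, chromosome 5, 90457443 to 90468167) carried 307 ± 35.7 scaled tags in young and 226 ± 39.6 in old libraries (SD, n = 5 each). The log2 difference was −0.45 (limma adjusted p = 0.14) and flipped its sign on tags per kb (0.02). Those of Apoa1, the main protein of high-density lipoprotein, held 2674 ± 540 and 2293 ± 279 (−0.21, limma adjusted p = 0.48). The region at Nnt, a mitochondrial gene with a known deletion in C57BL/6J mice, differed by −0.26 (limma adjusted p = 0.272; 0.26 on tags per kb). Being at a gene end, it does not check that deletion.

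The first comparison asked whether hepatocytes of old mice carry more or fewer acetylated regions. Young libraries had 27280 ± 2517 regions and old libraries 25857 ± 2818 (SD, n = 5 each), a difference of −1422 that lay within the spread between libraries (exact permutation p = 0.46). The regions covered 52.9 ± 7.49 Mb in young and 46.4 ± 6.96 Mb in old hepatocytes (exact permutation p = 0.183), with mean lengths of 1932 ± 125.6 and 1788 ± 99.7 bp (exact permutation p = 0.0952). Without old replicate 5 the differences were −261 regions and −3.46 Mb, without young replicate 4 −694 regions and without young replicate 3 −2285 regions. The share of tags inside called regions was 40.2 ± 6.62% in young and 31.9 ± 4.81% in old libraries (exact permutation p = 0.0476), and all 5 old libraries lay below the young median. That difference of −8.28 percentage points passed the threshold only with all libraries or without young replicate 3 or 5. Without any one of the other 8 libraries the exact p lay between 0.0556 and 0.167, with the smallest difference, −6.26 points, without young replicate 2.

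**Figure D1:**
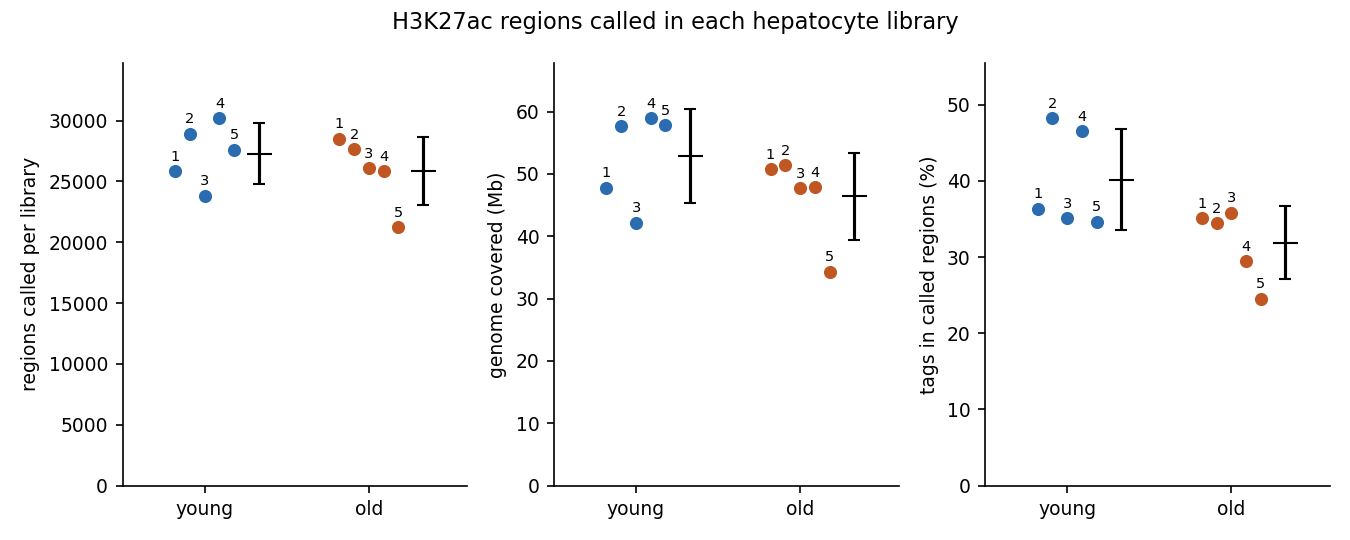
Number of called H3K27ac regions, genome covered in Mb and share of tags in called regions in percent for each library, numbered by replicate, with mean and SD per age (n = 5). The share of tags was 40.2 ± 6.62% in young and 31.9 ± 4.81% in old libraries. Regions, covered length and share of tags all overlapped between ages (lowest young share 34.63%, highest old share 35.84%).

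The second comparison asked whether the regions lay at different places in young and old hepatocytes. Of 31747 consensus regions, 53 were called in all 5 young libraries and in 0 old ones, and 11 in all 5 old and 0 young libraries. At gene ends, 5 of the young-only regions were named. The strongest was at Acadsb, an acyl-CoA dehydrogenase of branched-chain amino acid breakdown (chromosome 7, 131446968 to 131452629), with 103.5 ± 53.4 scaled tags in the libraries that called it (SD, n = 5). The others were at Gm40453 inside Pik3c2a (63.0 ± 17.8), at Ncoa4 and Timm23 (57.1 ± 18.7), at Cyp4a12a, a male-biased fatty acid hydroxylase (19.8 ± 13.5), and at Cript (17.5 ± 5.9). The sixth young-only region at a gene end was a weak one at Irf1, an interferon-induced transcription factor (16.5 ± 6.4), named after its value was seen. The strongest Irf1 gene-end region was called in all 10 libraries. The remaining young-only regions lay in gene bodies (25) or between genes (22). Of the old-only regions 5 lay in gene bodies, 6 between genes and 0 at gene ends. Each such region had a two-sided Fisher exact p of 0.00794, the smallest that 5 against 5 libraries can give. Over 31747 regions that is too large for so few of them to pass Benjamini-Hochberg adjustment, so single regions cannot be called. At an unadjusted p under 0.05 there were 390. The lists of libraries of the same age overlapped slightly more (mean Jaccard index 0.593) than those of different ages (0.574; one-sided exact p = 0.0317 over all splits into equal groups). The difference of 0.019 missed the threshold without young replicate 1 (0.0174, exact p = 0.0635) and without any one old library (0.0123 without old replicate 5 to 0.0196 without old replicate 2, exact p = 0.0556 to 0.135). It also missed it with the stricter score threshold (0.0082, exact p = 0.167) and where a library had to cover 0.5 of a region (0.0226, exact p = 0.0635). The count of 64 became 25 with the stricter threshold and 39 with lists of equal length. It was 97, 98, 100 and 106 without old replicate 1, old replicate 5, young replicate 3 and young replicate 5. Without any other single library it was 90 to 96, and without young replicates 1 and 3 together 258. With libraries left out fewer calls had to match, so these counts rise for that reason alone and cannot be set against 64. The excess of young-only over old-only regions shrank to 57 against 41 without old replicate 5 and to 26 against 13 with lists of equal length.

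The third comparison asked where the H3K27ac signal of shared regions differed with age. Among gene-end regions past the threshold whose values did not overlap between ages, the largest increases in old hepatocytes were at Tmem171 (chromosome 13, 98692751 to 98697091) and Il1f9, which encodes interleukin 36 gamma, a cytokine of the interleukin 1 family (chromosome 2, 24186215 to 24188482). Tmem171 went from 48.3 ± 25.5 to 184 ± 42.0 scaled tags (SD, n = 5 each; 4.26-fold, limma adjusted p = 0.0308). Il1f9 went from 21.7 ± 9.03 to 75.4 ± 16.2 (3.51-fold, limma adjusted p = 0.0249). Signal also rose at Spaca6, a sperm membrane protein gene (log2 difference 1.74 ± 0.31 SE), Col12a1, a collagen gene (1.65 ± 0.30), and the melatonin receptor gene Mtnr1a (1.43 ± 0.31). It rose by less at Pltp, the phospholipid transfer protein of plasma lipoproteins (1.17 ± 0.24), the mitotic kinesin gene Kif11 (1.10 ± 0.13) and the receptor gene Notch1 (1.08 ± 0.23). For these 6 genes limma's adjusted p ran from 0.00369 at Kif11 to 0.048 at Mtnr1a and Notch1. The largest decreases among such regions were at Tchh, the trichohyalin gene (chromosome 3, 93445622 to 93448304), and Hao1, the glycolate oxidase of liver peroxisomes (chromosome 2, 134549303 to 134555234). Tchh went from 329 ± 157 to 78.0 ± 38.6 (log2 difference −2.05, limma adjusted p = 0.0274) and Hao1 from 148 ± 40.5 to 54.5 ± 10.6 (−1.41, limma adjusted p = 0.0189). Signal fell by 1.33 on the log2 scale at Aacs, which activates the ketone body acetoacetate, although its sign turned on tags per kb (0.04). It also fell at the serine protease inhibitor genes Serpina1e (−1.16 ± 0.16 SE) and Serpina3k (−1.06 ± 0.16) and at the folate carrier gene Slc19a1 (−0.99 ± 0.19). Further decreases were at the mitochondrial phosphatase gene Pptc7 (−0.92 ± 0.13) and at the end shared by Coa6, a cytochrome oxidase assembly gene, and Tarbp1 (−0.91 ± 0.19). For these 6 regions, Aacs included, limma's adjusted p ran from 0.00876 to 0.0438. In each of these 16 regions the 5 libraries of one age lay above all 5 of the other, as the rule for naming them required. Of all 21 named regions past the threshold, 5 kept their call without old replicate 4, 6 without old replicate 1 or young replicate 2, and 20 without young replicate 1. On tags per kb of called length 2 of the 21 kept their call, 16 lost it and 3 reversed. Called length moved along, from a mean of 930 to 2907 bp at Tmem171 and from 4549 to 1767 bp at Hao1.

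**Figure D2:**
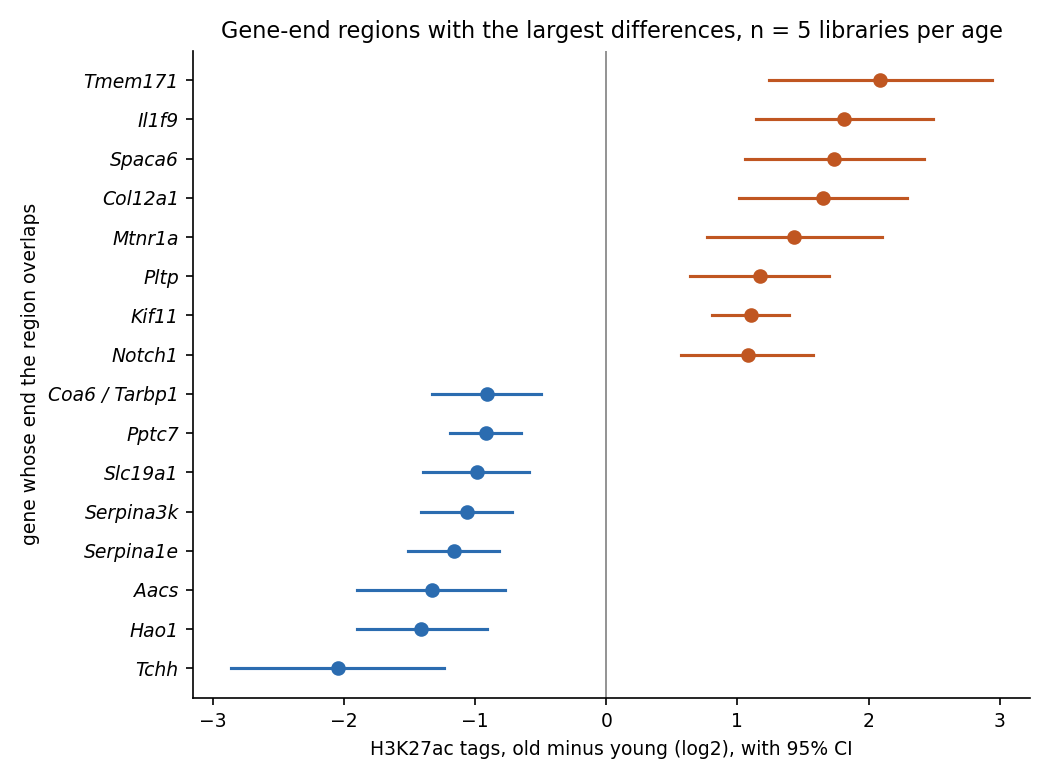
Log2 difference in scaled H3K27ac tags, old minus young, with 95% confidence interval for the 8 gene-end regions with the largest difference in each direction (n = 5 libraries per age). Values ran from 2.09 at Tmem171 to −2.05 at Tchh.

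In total 134 of 12550 regions called in all libraries passed the threshold, 67 higher and 67 lower in old hepatocytes, and 2156 had an unadjusted p under 0.05. The 5 values of each age did not overlap in 663 regions (5.3%), against an expected 0.79% if age labels were assigned at random. Regions of a library can vary together, and the spread of this share over random splits was not measured. Regions with higher signal were found at gene ends less often than the tested regions as a whole (22.4% against 53.8%, two-sided Fisher exact p = 1.99e-07), with 25 in gene bodies and 27 between genes. Of the regions with lower signal 50.7% lay at gene ends (Fisher exact p = 0.625), and the higher and lower sets differed in this share (Fisher exact p = 0.00114). The sets also differed in signal level, with a median over regions of 137.9 mean scaled tags in the higher and 320.4 in the lower set, so their places were not compared at equal level. The weakest of 5 equal groups by level held 23 higher and 6 lower regions, the strongest 10 and 26. Cyclic loess scaling, chosen after seeing the data, brought the median differences of these groups to −0.01 and 0. It called 104 regions, 59 higher and 45 lower, of which 92 were among the 134. The called length moved with the signal, at 1.4 times the young length in the higher and 0.63 times in the lower regions. On tags per kb of called length limma called 40 regions, 34 higher and 6 lower (85.0% higher against 50.0%), of which 15 were among the 134. With IP efficiency as a covariate limma called 0 regions (1666 at an unadjusted p under 0.05), while DESeq2 without the covariate called 619 and edgeR 119. IP efficiency itself differed between ages, so these fits cannot tell the calls apart from an effect of IP efficiency. Without centring, the median region differed by −0.31 and 725 regions passed, 28 higher and 697 lower (3.9% higher). All log2 differences given are therefore relative to the median region. Leaving out single libraries gave 30 regions (without old replicate 4) to 60 (without young replicate 5) for 9 of the libraries, but 255 without young replicate 1, and 259 without young replicates 1 and 3 together.

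The fourth comparison, to which the study's title points, asked whether genes of the interferon response and other gene groups differed with age. Interferon-stimulated genes had higher H3K27ac at their ends in old hepatocytes than other genes did, by 0.22 on the log2 scale, with 15 of 19 regions positive and a median of 0.11. The list passed by limma's camera (adjusted p = 0.00749; adjusted p = 0.192 with an estimated correlation). The region of Ube2l6, the enzyme that conjugates the interferon-induced modifier ISG15 (chromosome 2, 84794216 to 84803346), rose from 340.5 ± 62.1 to 520 ± 47.4 scaled tags (SD, n = 5 each; 1.54-fold, limma adjusted p = 0.0438). It was the only 1 of the 19 past the threshold over all regions, and 2 passed adjusted over the list alone. Values stood at 0.66 for Oasl1, of the oligoadenylate synthetase family (limma adjusted p = 0.0845), 0.44 for the exonuclease gene Isg20 (0.227; −0.05 on tags per kb) and 0.39 for the secreted glycoprotein gene Lgals3bp (0.242). Young libraries had called gene ends for 29.4 ± 3.0 and old libraries for 33.2 ± 1.1 of 48 interferon-stimulated genes (exact permutation p = 0.0238; adjusted p = 0.643 over 27 lists). Young replicate 1 had 25 and young replicate 3 had 28. Of the 37 genes with a gene-end consensus region, 14 were called in more old than young libraries, 3 in more young and 20 in as many of each. With young replicates 1 and 3 left out, a choice made after seeing the data, 9 were called in a larger share of the old and 4 in a larger share of the young libraries, with 24 equal.

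The list of interferon gamma and antigen presentation genes was higher by 0.11 (8 of 12 positive; limma camera adjusted p = 0.0261; adjusted p = 0.397 with an estimated correlation). None of its 12 regions passed alone, by limma over all regions (0) or adjusted over the list alone (0). The class I histocompatibility genes H2-K1, H2-Q4 and H2-D1 had 0.28, 0.19 and 0.19, with signs that flipped without centring (−0.01, −0.11 and −0.11), and H2-D1 also on tags per kb (−0.04). Psmb10, an immunoproteasome subunit sharing its region with Lcat, had −0.39. Interferon sensors and regulators did not pass as a list (0.03; limma camera adjusted p = 0.757). Their values were −0.23 for the kinase gene Jak1 (0.30 on tags per kb), −0.26 for Ticam1, which shares its region with Plin3, and 0.39 for the RNA sensor gene Tlr3. The NF-kB and inflammation list was higher by 0.25, with 7 of 12 regions positive and 0 past the threshold (limma camera adjusted p = 0.0261; adjusted p = 0.325 with an estimated correlation). Values were 0.54 at the region of Nfkbiz and Nxpe3 and 0.59 at the adhesion gene Icam1. Both the interferon gamma and the NF-kB list missed the threshold without young replicate 4 (camera adjusted p = 0.108 each), young replicate 5 (0.181 and 0.139), old replicate 4 (0.0795 and 0.0652) or old replicate 5 (0.068 each).

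Lists of clock genes, hepatocyte transcription factors, male-biased genes, bile acid genes, glucose metabolism and secreted proteins were lower in old hepatocytes. The circadian clock list differed by −0.25 (14 of 17 negative; limma camera adjusted p = 0.00872; adjusted p = 0.217 with an estimated correlation). In it the clock repressor gene Ciart fell by 0.87 on the log2 scale (limma adjusted p = 0.0269), and 7 regions fell adjusted over the list alone. Bhlhe41, Hlf and Clock had −1.28, −0.39 and −0.32 (limma adjusted p = 0.0775, 0.073 and 0.123). Hepatocyte transcription factors differed by −0.19 (18 of 22 negative; limma camera adjusted p = 0.00872; adjusted p = 0.192 with an estimated correlation). The region of Cebpd, shared with Spidr, fell by 0.55 on the log2 scale (limma adjusted p = 0.0433; 0.03 on tags per kb), and 6 fell adjusted over the list alone. The nuclear receptor gene Rxra, Klf15 and Thrb had −0.50, −0.42 and −0.36. Male-biased genes differed by −0.31 (13 of 15 negative; limma camera adjusted p = 0.00999; adjusted p = 0.192 with an estimated correlation). Of them Serpina1e passed the threshold and 2 did so adjusted over the list alone, with −0.55 at the glucuronosyltransferase gene Ugt2b1 and −0.43 at Gstp1. Bile acid genes differed by −0.23 (14 of 19 negative; limma camera adjusted p = 0.0139; adjusted p = 0.321 with an estimated correlation). Here Cyp27a1, the sterol 27-hydroxylase gene, fell by 0.62 on the log2 scale (limma adjusted p = 0.0274; 0.05 on tags per kb), and 5 fell adjusted over the list alone. Baat, which conjugates bile acids, the transporter gene Slco1b2 and Cyp7b1, also in the male-biased list, had −0.71, −0.51 and −0.44 (Cyp7b1 0.17 on tags per kb). Gluconeogenesis and glycolysis genes differed by −0.13 (16 of 19 negative; limma camera adjusted p = 0.0139; adjusted p = 0.216 with an estimated correlation). Of them 0 passed the threshold and 2 did so adjusted over the list alone, with −0.44 at the glucose-6-phosphatase gene G6pc and −0.47 at the insulin receptor gene Insr (0.17 on tags per kb). Genes of secreted hepatocyte proteins differed by −0.15 (29 of 34 negative; limma camera adjusted p = 0.0225; adjusted p = 0.611 with an estimated correlation). None (0) passed the threshold over all regions or over the list alone, and values were −0.61 at the growth factor gene Igf1 and −0.40 at Serpina1a.

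Lipid groups went the other way. Lipid synthesis and storage genes were higher by 0.13 (17 of 29 positive, 0 past the threshold; limma camera adjusted p = 0.0149; adjusted p = 0.192 with an estimated correlation). Examples were Fads1, a fatty acid desaturase gene, with 0.70 and Gpam, whose product starts triglyceride synthesis, with 0.43. Fatty acid oxidation and ketogenesis genes were higher by 0.14 (15 of 22 positive; limma camera adjusted p = 0.0195; adjusted p = 0.409 with an estimated correlation). Of them 0 passed the threshold and 1 did so adjusted over the list alone. Pdk4, which restrains pyruvate dehydrogenase, had 1.07 (limma adjusted p = 0.0542) and Angptl4, a lipoprotein lipase inhibitor gene, −0.36. In all, 11 of 22 lists passed with the preset correlation. By signal level, the median difference of all tested regions went from 0.11 in the weakest of 5 equal groups to −0.08 in the strongest.

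**Figure D3:**
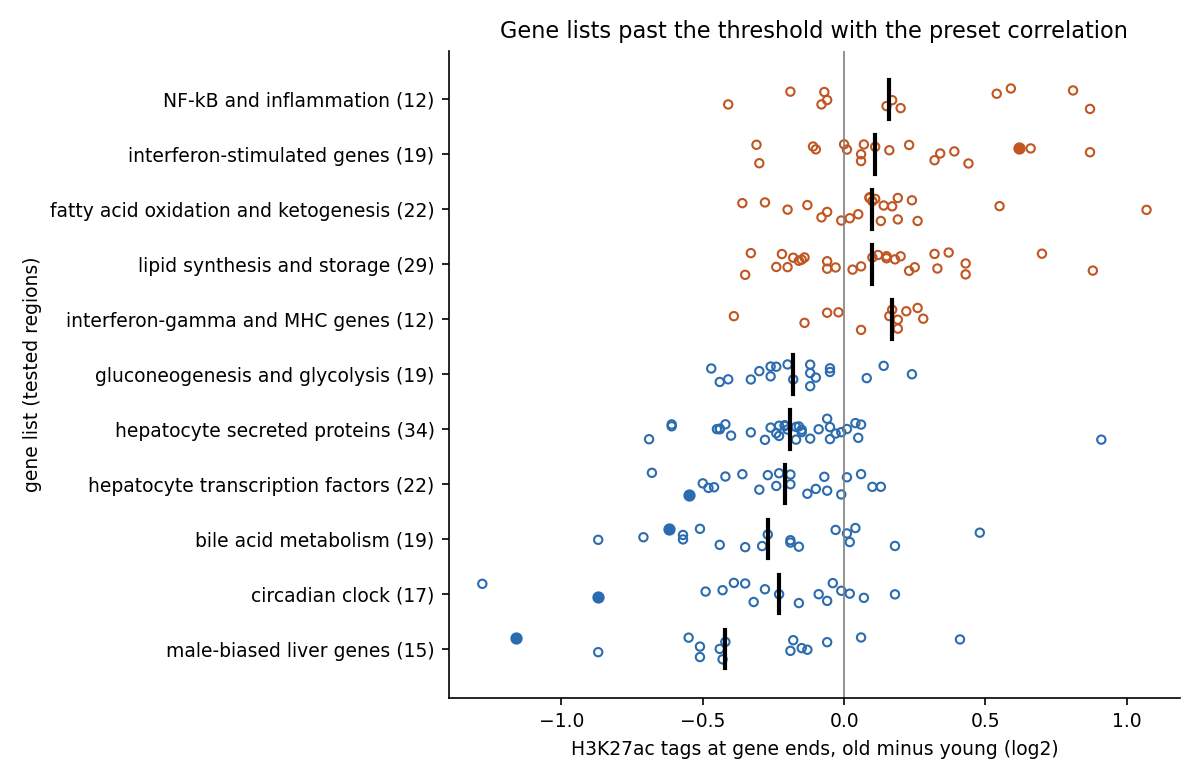
Log2 difference in scaled H3K27ac tags, old minus young, of every tested gene-end region (circles; filled where limma's adjusted p was under 0.05) in the 11 gene lists past the threshold with the preset correlation, with the median of each list (bar) and its number of regions. Interferon-stimulated genes had a median of 0.11 and male-biased genes one of −0.42.

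With an estimated correlation, and on tags per kb of called length, 0 of the 22 lists passed by camera, and fry called 5. With IP efficiency as a covariate 5 passed, among them the interferon-stimulated list (0.183, camera adjusted p = 0.0383). Without centring 3 passed, over whole gene spans 5 and without old replicate 5 6. Calls that ended without 1 library were those of transcription factors (young replicate 1, camera adjusted p = 0.0523), bile acid genes (young replicate 1, 0.0836; old replicate 5, 0.0646) and gluconeogenesis (old replicate 5, 0.06). The same held for fatty acid oxidation (young replicate 4, 0.108; old replicate 1, 0.112) and secreted proteins (young replicate 1, 0.395; old replicates 2, 4 and 5, 0.0835, 0.0795 and 0.101). With quantile scaling 6 lists passed as higher and 2 as lower, the male-biased and bile acid lists. Transcription factors, gluconeogenesis, secreted proteins and clock genes missed the threshold there (camera adjusted p = 0.127, 0.202, 0.215 and 0.0703). The first 3 of these also missed it with cyclic loess scaling (0.0558, 0.124 and 0.137), chosen after seeing the data. The interferon-stimulated, clock, male-biased and lipid synthesis lists passed without any one library and without young replicates 1 and 3 together. In that last setting 8 of the 11 lists kept their call and 3 lost it, and 10 lists passed in all.

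The other lists did not pass. Amino acid and urea cycle genes differed by −0.12 (limma camera adjusted p = 0.102), with −0.76 at Tdo2, the first enzyme of tryptophan breakdown, and −0.63 at the aminotransferase gene Got1. Immediate early genes, a sign of stress during isolation, differed by 0.09 (limma camera adjusted p = 0.127), with 0.37 at Fos (limma adjusted p = 0.073) and −0.57 at Myc. Both lists passed without young replicate 1 (camera adjusted p = 0.00404 and 0.04), young replicate 3 (0.0312 and 0.0444) or old replicate 1 (0.0387 each). Cytochrome P450 and xenobiotic genes went both ways (−0.09; limma camera adjusted p = 0.397), with 3 higher and 8 lower adjusted over the list alone and 0 over all regions. Values were 0.54 at the bilirubin-conjugating Ugt1a1 and −0.57 at Cyp2f2. In the acute phase and complement list (−0.09; limma camera adjusted p = 0.491) the interleukin 6 receptor gene Il6ra fell by 0.62 on the log2 scale (limma adjusted p = 0.0331). C1ra, sharing its region with C1rl, had −0.39. Heat shock and stress genes (−0.04; limma camera adjusted p = 0.945) included Hsph1 with −0.50 (0.04 on tags per kb) and Hsp90aa1 with −0.40. Cell cycle and p53 genes (−0.03; limma camera adjusted p = 0.945) included Trp53 with −0.36 and Sesn1 with −0.32. Fetal liver and liver cancer genes (−0.03; limma camera adjusted p = 0.64) included Glul, the glutamine synthetase gene, with −0.31 and the beta-catenin gene Ctnnb1 with −0.16. Female-biased genes had 3 tested regions, with a mean 0.11 above that of other genes and a median difference between ages of −0.19 (limma camera adjusted p = 0.901).

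Markers of other liver cells were little represented. Of the Kupffer cell and macrophage markers 4 regions were tested (−0.15; limma camera adjusted p = 0.491), among them Fcer1g (−0.23) and Cd68 (−0.30), whose regions also hold Apoa2 and Eif4a1, genes active in hepatocytes. Cholangiocyte markers, 7 regions, differed by −0.06 (limma camera adjusted p = 0.945), with −0.22 at Krt8 (0.18 on tags per kb). Markers of T, NK and B cells, of sinusoidal endothelium and of neutrophils had 0 regions called in all 10 libraries, and those of stellate cells and fibrosis 1, so these lists were compared only by called gene ends per library. Endothelial markers had 4.2 ± 1.5 in young and 4.2 ± 1.3 in old libraries (SD, n = 5 each; exact permutation p = 1). Stellate cell markers had 3.0 ± 1.6 and 3.2 ± 0.8 (exact permutation p = 1). Lymphocyte markers had 1.0 ± 0.7 and 1.2 ± 0.4 (exact permutation p = 1) and neutrophil markers 0.6 ± 0.5 and 1.0 ± 0.7 (exact permutation p = 0.643).

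A stretch of chromosome 19 held 3 regions with higher signal in old hepatocytes, singled out after its values were seen. One was at Btaf1, a regulator of the TATA-binding protein (36924775 to 36928175; log2 difference 0.82 ± 0.09 SE, limma adjusted p = 0.00261). The others were at Kif11 (37374873 to 37377067; 1.10 ± 0.13, limma adjusted p = 0.00369) and between genes (37261011 to 37266026; 1.01 ± 0.21, limma adjusted p = 0.0464). Input tags per kb in the same regions were also higher in old libraries, by 0.72, 0.58 and 0.64 (limma adjusted p = 1 each). Over all regions limma called 0 on the input, with 346 at an unadjusted p under 0.05. Between them the region shared by Cpeb3 and Marchf5 had −0.09 in H3K27ac and −0.11 in the input. The next tested region, between genes (37241494 to 37244069) had 1.41 ± 0.57 SE in H3K27ac (limma adjusted p = 0.227) and 1.30 ± 0.34 in the input (limma adjusted p = 1). Its input tags per kb ran from 0.2 to 4.98 in young and from 6.42 to 8.91 in old libraries.

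**Figure D4:**
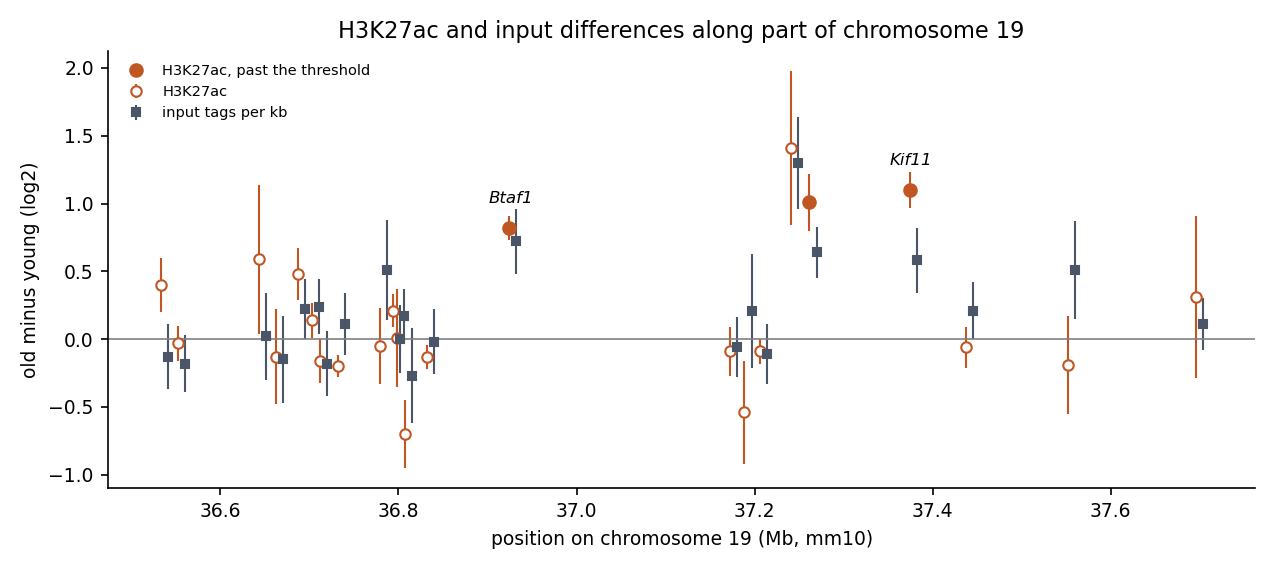
Log2 difference, old minus young, with SE, of H3K27ac (circles; filled where limma's adjusted p was under 0.05) and of input tags per kb (squares) in the regions tested along part of chromosome 19 in mm10 (n = 5 libraries per age). At Btaf1 and Kif11 the H3K27ac differences were 0.82 and 1.10 and the input differences 0.72 and 0.58. The largest input difference, 1.30, was in a region between them that was not past the threshold.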

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

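The tests of locus copies, of leaving out young replicates 1 and 3, of depth, of time of day and of the input of young replicate 1 were chosen only after the results were seen.

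Interferon-stimulated genes had more H3K27ac at their ends in old than in young hepatocytes by 0.22 on the log2 scale relative to other genes, with 1 of 19 regions past the threshold. As a list they passed by camera with the preset correlation (adjusted p = 0.00749) but not with an estimated one (0.192) or by fry (0.123). The tables argued against a trend with signal level and against young replicates 1 and 3 as the whole cause: the difference was 0.209 after cyclic loess scaling and 0.294 without young replicates 1 and 3, in which several interferon-stimulated gene ends were not called. Immune cells in the old preparations stayed open, because called gene ends of macrophage and lymphocyte markers differed by 0.4 per library (7.4 ± 1.1 in young and 7.8 ± 0.8 in old, SD, n = 5 each; exact permutation p = 0.762) and 41 of the 50 markers had no gene-end consensus region. On tags per kb of called length the difference was 0.055 and no longer past the threshold, so that wider called regions may carry most of it. Age and substrain, which the design does not separate, both remain open as biological accounts and were not tested.

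On chromosome 19 the 3 regions with higher H3K27ac in old hepatocytes, spread over 452 kb, stood out because the input, which the main signal comparison does not use, was also higher in them in all 5 old libraries than the young median, by 0.72, 0.64 and 0.58. The mean difference was 0.65 in the input and 0.98 in H3K27ac (1.57-fold and 1.97-fold), so the input difference amounted to 66% of the other. Extra copies of parts of this stretch in the old C57BL/6J mice are a candidate explanation, since copy number differences there are known among C57BL/6J mice, although the input difference did not pass a threshold in any single region. Scaling alone was argued against, since the largest adjusted p of the 3 regions was 0.0458 with cyclic loess scaling (all 3 past the threshold), but with IP efficiency as a covariate Kif11 kept a difference of 1.13 and lost the call, as every region did. Input values came only from each library's called regions. Input and H3K27ac differences correlated by 0.38 over the 134 regions past the threshold and by 0.19 over all tested regions. A region past the threshold on chromosome 1 (42532039 to 42533806) also had an input difference of 0.67, with every old library above the young median. Whether the mice were bred from carriers of extra copies on chromosome 19 cannot be read from the labels, and age itself stays open.

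Young replicate 1 lay apart from the rest, with the lowest mean correlation with its own group (0.829) and 445 gene-end regions missing (6.2%) that all 9 other libraries had. Its IP efficiency of 36.36% and its 8830854 tags lay inside the range of the others, which argues against low depth. An admixture of other cells stayed open: its 14 called gene ends of their markers lay below the highest other library (20), but the gene ends missing in it lower such a count, so the bound set for that test was wrong, and cholangiocyte and macrophage markers were the lists most raised in it over the other young libraries (0.82 and 0.81). Another time of day at isolation stayed open: its clock regions deviated from the other young libraries at the 94.8th percentile of matched random sets, within error of the bound of 95 set for that test, with −1.14 at Dbp, −1.21 at Per3 and 0.75 at Nfil3. A strong gene-end signal in its input, which raises the bar for a call, failed a first test, since the missing gene ends had fewer H3K27ac tags in the other libraries than those called (127.4 against 249.9). A second test, set up once the first had failed, compared gene ends of matched H3K27ac tags. It gave 0.43 ± 0.02 SE more input on the log2 scale at the missing ones. The same value was 0.37 ± 0.02 in young replicate 3, and from −0.36 ± 0.14 (young replicate 5) to 0.30 ± 0.14 (young replicate 2) in the other libraries. Young replicate 3, with a higher ratio of input at gene ends to elsewhere (3.61 against 2.44), lacked fewer regions (363). The input therefore remains a hypothesis that these tests do not settle.

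Among 174 groups of 5 libraries examined for a library far from the other 4, 15 had one, where chance alone gives about 1 in 20, or 8.7. Old replicate 5 covered 34.33 Mb, against 47.68 Mb or more in the other old libraries. Young replicate 5 had 15544145 tags and an estimated fragment length of 620 bp, and old replicate 4 one of 444 bp against 440 bp in the other old libraries. Young replicate 1 had the highest young value at Myc (545 scaled tags) and at Glul (480.5) and the lowest at Klf15 (2192). Young replicate 3 had the highest young value at Slc19a1 (323.1) and at Cebpd (637.4) and the lowest at Isg20 (91.78). Old replicate 1 had the highest old value at Serpina3k (322.4) and the lowest at Hsp90aa1 (247), and old replicate 5 the highest at Cyp7b1 (288.1), Glul (382.9) and Eif2s3y (79.78).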

How the results depend on the processing

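Tests of cyclic loess scaling, input subtraction, library weights, whole gene spans, IP efficiency itself, IP efficiency as a covariate for the lists and the joint removal of young replicates 1 and 3 were chosen only after seeing the data. The numbers of regions and the covered length missed the threshold under every alternative run. Unless given, the cause was not tested.

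Replicate numbers showed no strong pairing of the libraries, although weaker shared handling is not excluded. Same-numbered libraries correlated by −0.01, 0.11, 0.18, −0.05 and 0.07 in their deviations, and 1 of 5 young libraries correlated best with its own number. With the replicate block the IP efficiency difference stayed at −8.28 (exact p = 0.125) and the overlap difference at 0.0188 (exact p = 0.0625). No exact test with the block can give a p below 0.0625, so none could pass the threshold, and the overlap reached that floor. Regions with different signal numbered 74 with the block, while 11 of 11 lists kept their call. The count of regions of one age uses no model, so the block cannot change it.

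Leaving out single libraries gave −9.66 to −6.26 points for IP efficiency, 0.0123 to 0.0222 for the overlap, 90 to 106 regions of one age, where fewer libraries had to match, 30 to 255 regions with different signal and 6 to 13 lists. Without young replicates 1 and 3 there were 258 regions of one age, again with fewer libraries to match, and 259 with different signal. The overlap difference was 0.0082 with the stricter score and 0.0226 where 0.5 of a region had to be covered, and regions of one age numbered 25 with the stricter score and 39 with lists of equal length, which hold fewer regions.

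Regions with different signal numbered 725 as deposited (the median shift of −0.31 then counts as signal), 40 on tags per kb, 216 with uncalled values at the floor (17259 regions tested), 0 with IP efficiency as a covariate, 608 with library weights and 619 by DESeq2. Between 92 and 173 were called by edgeR, quantile and loess scaling, a pseudocount of 10, input subtraction and the upper regions by mean. The lists past the threshold numbered 3 as deposited, 0 on tags per kb, 5 with IP efficiency as a covariate, 5 over gene spans, 0 by camera with an estimated correlation and 5 by fry, and 8 to 11 in the remaining settings. On tags per kb Aacs, Cebpd and Cyp27a1 reversed to 0.04, 0.03 and 0.05, and 2 of 21 named regions kept their call. With 5 libraries per age, 1.5-fold differences were recovered in 19.4% of simulated regions.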

Other observations

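The chance splits were planned, and the test of the transcription factor and bile acid lists under loess scaling was set up for both lists together and reported for each after its result was seen.

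Of 48 interferon-stimulated genes 20 had a gene end called in all 10 libraries and 11 had no gene-end consensus region. Among the 11 were the oligoadenylate synthetase genes Oas2 and Oas3, and also Mx1, Mx2 and Oas1b, which the table of protein-coding genes did not hold, all named after their values were seen.

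The lists of transcription factor and bile acid genes were lower in old hepatocytes by camera with the preset correlation, with 1 of 22 and 1 of 19 regions past the threshold, but missed it with an estimated correlation (adjusted p = 0.192 and 0.321). With cyclic loess scaling the difference of the transcription factor list went from −0.19 to −0.136 at the same spread between its regions (SD 0.22 in both), and its call ended (camera adjusted p = 0.0558) with that smaller difference, so the trend with signal level cannot be told apart from a change of that list. The bile acid list stayed past the threshold at −0.206, which argues against that trend as its whole cause, although its call ended with IP efficiency as a covariate (−0.212), without young replicate 1 (camera adjusted p = 0.0836) and without old replicate 5 (0.0646).

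The number of regions with different signal was 134 in the real split and at most 33 in the others (1 of 100 splits as large, the real one). Not every possible split was drawn, so chance is unlikely for this number but not strictly excluded. The splits cannot tell age from IP efficiency, which differed between ages. With IP efficiency as a covariate limma called 0 regions. For regions called at one age only the real split also gave the most, by a narrower margin (64 against 49, 1 of 100 splits). The counts of 39 with lists of equal length and 25 with the stricter score were not set against splits of their own. Chance is therefore not excluded for these regions. For the number of gene lists, 2 of 100 splits gave as many as the real 11. Chance is not excluded there, since a split that mixed the ages gave 12.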
